A study of Mus musculus with 6 samples.

How the data were processed

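Bulk RNA sequencing was done on liver of 6 male mice. Per the labels, the mice were put on a high-fat diet at 8 weeks of age and kept on it for 20 weeks, and the series' design text describes 3 animals per group: floxed G3bp1 controls without Cre, and animals carrying the same floxed alleles with Cre recombinase under the albumin promoter, which is active in hepatocytes. Poly-A RNA was enriched with oligo(dT) beads, per the labels' protocols, and libraries were sequenced as read pairs.

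Each deposited file holds the estimated count, the TPM, the length and the effective length of 115221 transcripts in 1 library, in the column layout of Salmon, per the file headers. The version, options and transcriptome behind these files are not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.2.5, RSEM 1.2.8, DESeq and the build GRCm38 were used, with no role stated, and the notes do not name Salmon. The deposited estimated counts are not scaled to depth. The deposited TPM values, per the file headers, are scaled to the same total within each library. The fragment length implied by the effective lengths was 242, 255 and 248 bases in control replicates 1 to 3 and 259 and 262 bases in knockout-labelled replicates 2 and 3, whereas it was exactly 250 in knockout-labelled replicate 1, where a transcript of 100 bases has an effective length of 3.50 in place of 100. That library was therefore quantified with another fragment length setting than the other 5.

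Transcripts were assigned to genes with GENCODE M21, an annotation of GRCm38. Of the transcript identifiers, 113664 matched without their version, 13 of these also with it, and 1557 matched no gene and were left out. The length in the files equalled that in the annotation for 99.2% of the matched transcripts. Because versions differ, the annotation behind the files is a different one, and only the position of G3bp1 is given, on GRCm38. Estimated counts were summed over the transcripts of each of 35082 genes and rounded to whole numbers. Without stated use of strand, reads of overlapping and antisense genes, and of near-identical copies, cannot be told apart in these sums.

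Totals ran from 20899135 to 21750007 estimated counts per library. Genes were filtered with filterByExpr, which left 12497, scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values given per library are scaled with the TMM factors. Of 42 gene lists written before the data were examined, 26 of pathways and 16 of cell types, the 38 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. For a list, medians, counts of members and values of single genes are edgeR log2 differences, whereas the means given for an alternative or a left-out library, and the values they replace, are of log2 CPM differences with that prior count. The 4 lists with fewer tested members, of pancreatic acinar, muscle, mesothelial and gallbladder or intestinal genes, have no test. Principal components used the 500 most variable genes.

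Named genes followed a rule fixed before the data were examined. It takes G3bp1 and G3bp2, then genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out predicted names and pseudogenes. Since fewer than 5 genes passed in either direction, it took the 5 genes with the smallest p in each direction under the same filters, which lie below the threshold. For each list described, it takes up to 4 members with the smallest p. Some genes that the rule takes are not reported here.

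The alternatives fixed beforehand were other scalings and filters, DESeq2 1.42.0, limma voom with and without sample weights, a transcript length offset, a minimum fold, each library left out, the replicate number as a block, and transcripts in place of genes. Added after seeing the data were library totals without TMM, protein-coding genes alone, a term for a division of the libraries seen in their transcripts, removal of each library's trend over transcript length and GC content (loess, span 0.5, degree 2), and both of the last together. That division was read from the counts themselves after all 10 divisions of the 6 libraries into sets of 3 had been compared, so a fit that uses it is descriptive.

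The tests were checked on simulated counts drawn from the means, library sizes and dispersions of the 12497 tested genes, with 200 genes changed. Of 50 genes changed 1 log2 unit, edgeR called 5 and DESeq2 18. At 2 log2 units edgeR called 38 of 50 and DESeq2 43, and at 4 log2 units both called all 50. Among 12297 unchanged genes edgeR called 17 and DESeq2 38. A shifted list was called by camera and none of 20 unshifted lists was, with genes drawn independently. This does not check camera for lists whose genes vary together. Among the 10 lists called in the data the estimated correlation ran from -0.02 (pericentral hepatocyte) to 0.79 (Kupffer cell and macrophage). Replicates of a group differed far beyond counting noise in every pair, with a chi-square per degree of freedom of at least 103, so all 6 were counted as separate samples.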

Results

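Liver transcripts were measured in 6 male mice fed a high-fat diet for 20 weeks, to compare 3 floxed control animals with 3 animals labelled as a hepatocyte knockout of G3bp1. G3BP1 is an RNA-binding protein that nucleates stress granules, which are cytoplasmic assemblies of stalled mRNA and protein. Totals were 20899135, 21750007 and 21026146 estimated counts in control replicates 1 to 3 and 21515961, 21206991 and 21019038 in knockout-labelled replicates 1 to 3. Mitochondrially encoded genes took 7.40%, 7.64% and 7.22% of counts in the controls and 7.57%, 9.19% and 10.2% in the knockout-labelled libraries. The 10 most abundant genes took between 24.9% and 28.3% of counts, and albumin (Alb) was the most abundant gene in every library.

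G3bp1 (ENSMUSG00000018583; chromosome 11, 55469685 to 55504838, plus strand, GRCm38) was not detectably lower in the knockout-labelled libraries. It measured 44.1, 34.8 and 40.5 CPM in control replicates 1 to 3 and 44.0, 30.0 and 31.5 CPM in knockout-labelled replicates 1 to 3, a mean of 39.8 ± 4.69 against 35.2 ± 7.70 (SD, n = 3 each). The log2 difference was -0.18 with a standard error of 0.22 (edgeR adjusted p = 0.91), and its 95% interval with 4 residual degrees of freedom ran from -0.78 to 0.42. In the deposited TPM the order of the means turned, with 4.20 ± 0.65 in controls and 4.75 ± 0.56 in the knockout-labelled libraries (SD, n = 3 each), and with library totals in place of TMM factors the log2 difference was 0.07. Neither uses TMM factors. These were 0.90, 0.84 and 1.00 in control replicates 1 to 3 and 1.08, 1.07 and 1.14 in knockout-labelled replicates 1 to 3. Leaving them out raised the median log2 difference of all genes by 0.26. The G3bp1 difference was -0.37 with the length and GC trend removed, -0.31 with sample weights in limma voom and -0.06 with the library division as a term. Nearly all counts lay on 1 transcript of 6703 bases, and the part of the gene removed by Cre is not given in the sources used here, so a sum over the whole transcript does not check the loss of an exon. Since the level of the targeted gene does not set the groups apart, they are called control and knockout-labelled throughout. G3bp2, the paralogue of G3bp1, measured 29.6 ± 8.75 CPM in controls and 38.5 ± 11.2 CPM in the knockout-labelled libraries (SD, n = 3 each; log2 difference 0.38, edgeR adjusted p = 0.86). With 1 library left out the G3bp2 difference ran from 0.14, without knockout-labelled replicate 3, to 0.56, and it was 0.15 without control replicate 1. It was 0.65 with library totals in place of TMM factors, 0.20 with the library division as a term and 0.16 with that term and the length and GC trend removed.

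**Figure D1:**
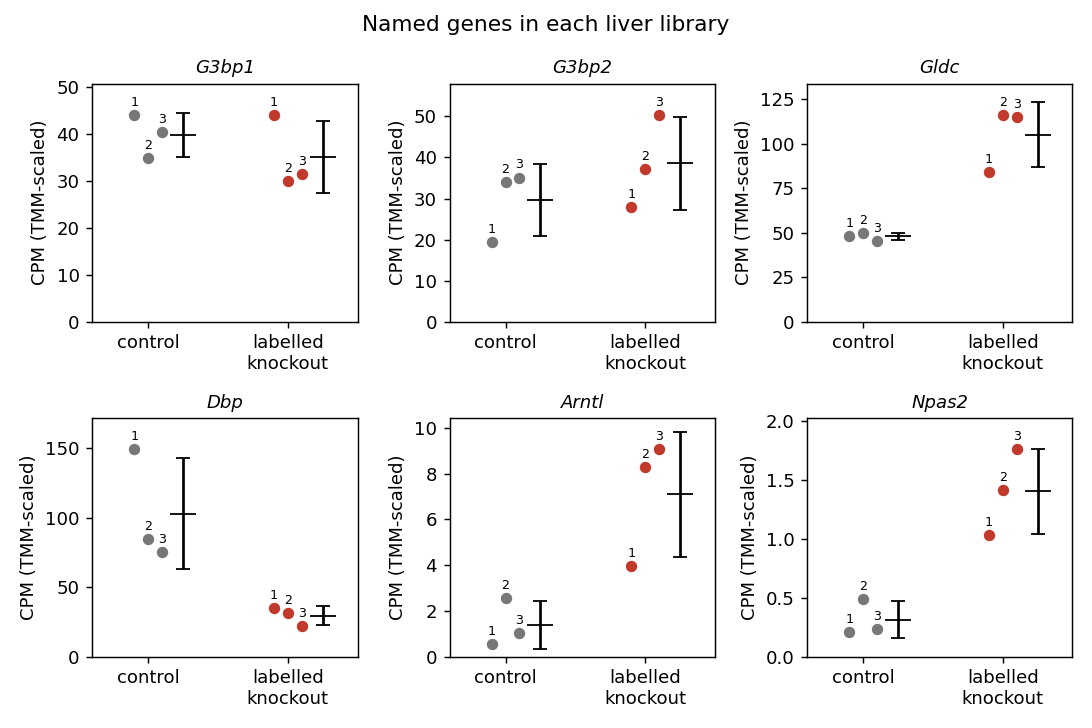
TMM-scaled CPM of 6 genes in each library, with replicate numbers beside the points and the mean and SD of 3 libraries as bars. G3bp1 overlaps between the groups, at 34.8 to 44.1 CPM in controls and 30.0 to 44.0 in knockout-labelled libraries, whereas Gldc, Dbp, Arntl and Npas2 do not overlap but lie below the threshold over all genes by edgeR. DESeq2 called Gldc, Dbp and Arntl over all genes.

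No gene passed the threshold over all 12497 genes tested by edgeR. The edgeR test called 0 genes higher and 0 lower, with a smallest adjusted p of 0.84, and 568 genes had an unadjusted p under 0.05, of which 331 were higher and 237 lower in the knockout-labelled libraries. The groups did not overlap for 9.34% of genes, where chance gives 10%. DESeq2 called 7 genes higher and 5 lower, limma voom called 0, and leaving out knockout-labelled replicate 1 gave 2 higher and 1 lower by edgeR.

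The genes with the smallest p, all below the threshold with an edgeR adjusted p of 0.84, included an enzyme of glycine breakdown and a clock-controlled transcription factor. Gldc, the glycine decarboxylase of the glycine cleavage system, measured 48.0 ± 2.22 CPM in controls and 105 ± 18.4 CPM in the knockout-labelled libraries (SD, n = 3 each; log2 difference 1.13, standard error 0.21). Slc17a8 and Fam13b had log2 differences of 0.97 and 1.18. Cyp2c40 had 0, 2 and 0 counts in control replicates 1 to 3 and 103, 22 and 25 in the knockout-labelled libraries, a ratio of 62.5 with a counting interval of 17.0 to 521 (95%, exact). That interval covers counting error only and holds no spread between animals. Knockout-labelled replicate 1 carried 103 of the 150 counts, and without it the ratio was 29.4. Without control replicate 3 the ratio was 39.9. Without control replicate 2, which leaves the controls at 0, the ratio to an assumed floor of 3 counts over the group was 28.6. The lower end of the exact 95% counting interval there was 22.9. Cyp2c40 belongs to a family of near-identical genes among which reads can be divided. Of 19 female-biased liver genes Cyp2c40 was the 1 that passed adjusted over the list alone, whereas 12 lay below 0 with a median of -0.22 and a mean of 0.13 in edgeR log2 differences, and the list was not called (camera adjusted p = 0.79). On the lower side, Dbp, a clock-controlled transcription factor, measured 103 ± 40.2 CPM in controls and 29.6 ± 6.78 CPM in the knockout-labelled libraries (log2 difference -1.80, standard error 0.32). Wee1, a cell cycle kinase, and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, had log2 differences of -1.36 and -1.86. Slc46a3 had -0.78. Of these genes, DESeq2 placed Gldc, Cyp2c40, Dbp and Ppp1r3g past its threshold.

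Among the gene lists, those of the ribosome and the respiratory chain lay lower in the knockout-labelled libraries. Of 50 ribosomal protein genes 49 had a log2 difference below 0, with a median of -0.46, led by Rpl35 (-0.69), Rps28 (-0.68), Rpl24 (-0.73) and Rpl11 (-0.66), and 7 members did not overlap between groups. Of 43 nuclear genes of the respiratory chain 39 lay below 0, with a median of -0.41, led by Ndufa1 (-0.58), Cox6a1 (-0.68), Ndufa9 (-0.50) and Cox8a (-0.54). No member of either list passed the threshold, over all genes or adjusted over the list alone. Camera with the preset correlation gave adjusted p = 1.49e-15 and 2.81e-10, and with an estimated correlation the adjusted p was 0.88 for both. The median deviation of the ribosomal list from the mean of the libraries was 0.16, 0.35 and 0.32 in control replicates 1 to 3, 0.27 in knockout-labelled replicate 1, and -0.25 and -0.74 in replicates 2 and 3. That of the respiratory chain list was 0.20, 0.15 and 0.25 in control replicates 1 to 3 and 0.14, -0.27 and -0.52 in knockout-labelled replicates 1 to 3. Genes with transcripts of up to 800 bases deviated likewise as a class, by 0.17 to 0.33 in the controls and knockout-labelled replicate 1 and by -0.34 and -0.62 in knockout-labelled replicates 2 and 3. The share of transcripts with counts above 0 was 36.3% and 37.8% in knockout-labelled replicates 2 and 3 and 30.2% to 31.2% in the other libraries. Their mitochondrial shares, given above, were also the highest. With each library's trend over transcript length and GC content removed, chosen after seeing the data, the mean log2 difference of the ribosomal list went from -0.51 to -0.11 and that of the respiratory chain list from -0.37 to -0.08, and neither was called. Without knockout-labelled replicate 3 the means were -0.27 and -0.24.

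**Figure D2:**
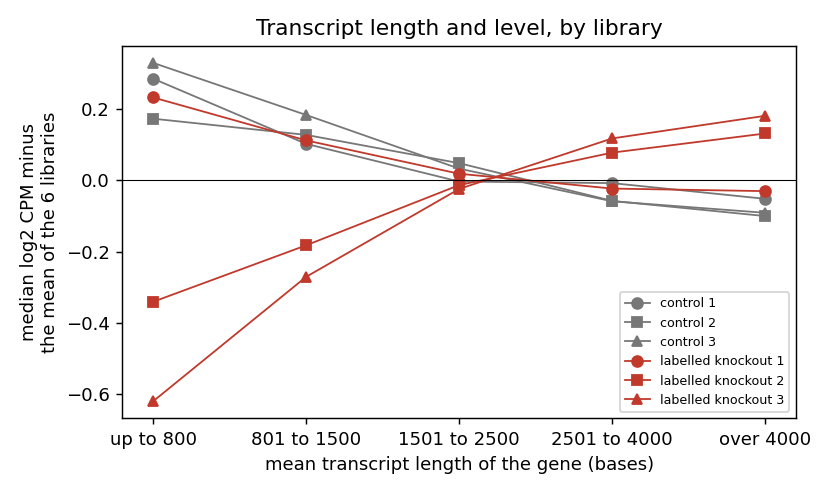
Median log2 CPM minus the mean of the 6 libraries, for genes grouped by mean transcript length in bases, with 1 line per library. In the class up to 800 bases knockout-labelled replicates 2 and 3 sit at -0.34 and -0.62, and the other 4 libraries between 0.17 and 0.33.

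Genes of fat synthesis, stress granules and interferon signalling lay higher on balance. In de novo lipogenesis 14 of 21 members lay above 0 with a median of 0.40, and 6 did not overlap between groups (29%, where chance gives 10%). Acaca and Acacb, the acetyl-CoA carboxylases, had log2 differences of 0.60 and 0.83, the desaturase Scd1 1.22 and the elongase Elovl5 0.60. Of 25 stress granule genes 19 lay above 0 with a median of 0.35, led by Caprin1 (0.58), Tial1 (0.45) and Atxn2l (1.12). Its median deviation was -0.08, -0.04 and -0.10 in control replicates 1 to 3 and -0.12, 0.29 and 0.20 in knockout-labelled replicates 1 to 3, so that knockout-labelled replicate 1 lay below every control. That of lipogenesis was -0.14, -0.20 and -0.03 in control replicates 1 to 3 and 0.21, 0.26 and -0.09 in knockout-labelled replicates 1 to 3. Of 33 interferon and innate sensing genes 27 lay above 0 with a median of 0.39, led by Irf9 (0.67), Stat2 (0.75), Rsad2 (0.95) and Irf1 (0.72), and none was free of overlap between groups. Camera with the preset correlation gave adjusted p = 0.029, 0.011 and 0.029 for the 3 lists, and with an estimated correlation the adjusted p was 0.88 for each. No member of these lists passed the threshold over all genes or adjusted over the list alone. The interferon list's mean log2 difference was 0.03 without knockout-labelled replicate 3, in place of 0.33, that of lipogenesis was 0.03 without knockout-labelled replicate 1, in place of 0.20, and 0.07 without control replicate 2. The lipogenesis mean was 0.44 without knockout-labelled replicate 3 and 0.35 without control replicate 3, and the interferon mean was 0.63 without knockout-labelled replicate 2 and 0.51 without control replicate 3. Both calls were also lost without control replicate 1, that of lipogenesis without knockout-labelled replicate 2, and that of the interferon list without control replicate 2 or knockout-labelled replicate 1. The lipogenesis mean was 0.20 without control replicate 1 and 0.15 without knockout-labelled replicate 2. The interferon mean was 0.25 without control replicate 1, 0.24 without control replicate 2 and 0.33 without knockout-labelled replicate 1. The stress granule call was lost without control replicate 1, at a mean of 0.25, and without knockout-labelled replicate 2, at 0.19, in place of 0.27. With each library's trend over transcript length and GC content removed, the lipogenesis call ended at a mean of 0.10 (camera adjusted p = 0.16) and the stress granule call at 0.17 (camera adjusted p = 0.071). With the library division as a term the stress granule call ended at 0.19 (camera adjusted p = 0.077) and the lipogenesis mean was 0.36. The interferon call ended with library totals in place of TMM factors, at a mean of 0.58 (camera adjusted p = 0.19).

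Macrophage, red blood cell, male-biased and pericentral hepatocyte genes also lay lower on balance, while 17 of 23 periportal hepatocyte genes lay above 0 with a median of 0.19 and were not called (camera adjusted p = 0.10). All 15 Kupffer cell and macrophage markers lay below 0 with a median of -0.61, led by C1qa (-0.64), Cd5l (-0.62), Cd68 (-0.63) and Itgam (-0.82), and so did all 12 markers of lipid-associated macrophages with a median of -0.49, led by Spp1 (-0.60) and Lpl (-0.74). No marker of either list was free of overlap between the groups. Without control replicate 3 the mean log2 difference was 0.07 for Kupffer cell and macrophage markers, in place of -0.41, and -0.04 for lipid-associated macrophage markers, in place of -0.38. The former was -0.77 without control replicate 1 and the latter -0.73 without knockout-labelled replicate 1. Control replicate 3 also stood highest for neutrophil, T and NK cell and inflammatory cytokine genes, with median deviations of 1.72, 0.92 and 0.84, lists that were not called. All 6 red blood cell markers lay below 0 with a median of -0.95, and Hbb-bt passed adjusted over the list alone (adjusted p = 0.0498, edgeR) but not over all genes. The median deviation of the red blood cell list was 0.76, -0.21 and 0.82 in control replicates 1 to 3 and 0.24, -0.67 and -0.78 in knockout-labelled replicates 1 to 3, so that control replicate 2 lay below knockout-labelled replicate 1. Its mean log2 difference was -0.92, and it was -0.51 with the length and GC trend removed, -0.60 with the library division as a term and -0.30 with both. It was called in each with the preset correlation, whereas in the main fit with an estimated correlation the adjusted p was 0.88. Of 27 male-biased liver genes 23 lay below 0 with a median of -0.80, led by Cyp7b1 (-1.48) and Mup12 (-2.21), with Elovl3 at 1.02, and the mean edgeR log2 difference was -0.84. The mean log2 CPM difference of the male-biased list, in which low counts are shrunk, was -0.53, and it was 0.08 without control replicate 2. It was -1.32 without control replicate 3 and -0.87 without knockout-labelled replicate 3. Of 23 pericentral hepatocyte genes 16 lay below 0 with a median of -0.18, led by Cyp1a2 (-0.96), Cyp2c37 (-0.86) and Cyp2a5 (-1.18), 1 transcript of which had at most 2.05 counts in control replicate 2 and knockout-labelled replicates 2 and 3 and at least 1101 in the other libraries. The mean log2 CPM difference of the pericentral list was 0.05 with library totals in place of TMM factors, a scaling that raised the median of all genes by 0.26 and left the list called lower relative to other genes (camera adjusted p = 0.0055). Camera with the preset correlation gave adjusted p from 8.73e-05 to 0.029 for these 5 lists, and with an estimated correlation the adjusted p was 0.88 for each. The male-biased call was also lost without control replicate 1, at a mean of -0.34, or knockout-labelled replicate 1, at -0.24, the Kupffer cell and macrophage call without knockout-labelled replicate 1, at -0.49, the lipid-associated macrophage call without knockout-labelled replicate 2, at a mean of -0.15, or 3, at -0.28, and the pericentral call without control replicate 2 or knockout-labelled replicate 1. The pericentral mean was -0.18 and -0.22 in these 2 fits, in place of -0.21. The lipid-associated macrophage call also ended with the length and GC trend removed, at a mean of -0.34 (camera adjusted p = 0.096), and with the library division as a term, at -0.14 (camera adjusted p = 0.17). The Kupffer cell and macrophage call ended with both together, at -0.26 (camera adjusted p = 0.079), and the male-biased mean was -0.98 with the library division as a term. The other 28 lists tested did not pass.

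**Figure D3:**
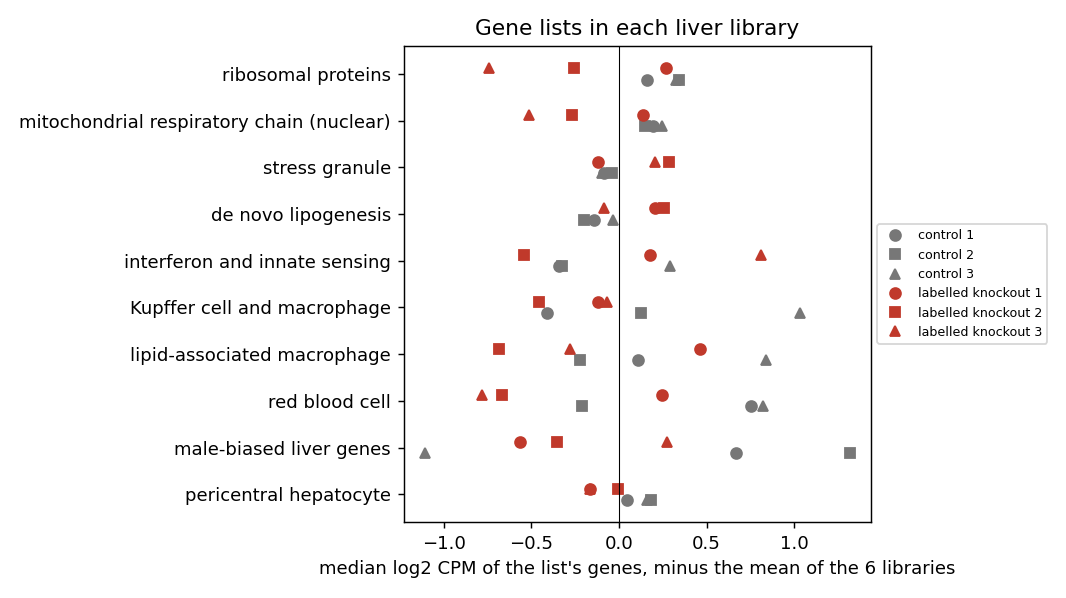
Median log2 CPM of the genes of 10 lists minus the mean of the 6 libraries, 1 point per library. Knockout-labelled replicate 1 lies among the controls for ribosomal proteins, at 0.27, and 1 control library, replicate 3, stands at 1.03 for Kupffer cell and macrophage markers.

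Among core clock genes Arntl and Npas2 lay higher and Dbp lower, while the list as a whole did not pass. Of 21 members 3 passed adjusted over the list alone and 0 over all genes by edgeR, while DESeq2 called Dbp and Arntl over all genes (adjusted p = 0.00041 and 0.026). Dbp was lower, as given above, and Npas2 and Arntl, which encode partners in activating complexes of the clock, had log2 differences of 2.15 and 2.36. For both, the edgeR adjusted p over the list alone was 0.019. Arntl measured 0.53, 2.57 and 1.05 CPM in control replicates 1 to 3 and 3.97, 8.28 and 9.05 CPM in knockout-labelled replicates 1 to 3. Npas2 measured 0.21, 0.49 and 0.24 CPM in control replicates 1 to 3 and 1.04, 1.42 and 1.76 CPM in knockout-labelled replicates 1 to 3. A floor of 3 counts equals 0.14 to 0.16 CPM in the controls, so few counts set the size of the Npas2 difference. Nfil3 had a log2 difference of 0.88 and did not pass adjusted over the list alone. The groups did not overlap for 6 of the 21 members (29%, where chance gives 10%).

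The first principal component did not order the libraries by group, and the second did. The first, with 47.5% of the variance, placed control replicates 1 and 3 and knockout-labelled replicate 1 at -14.7, -12.0 and -41.0, and control replicate 2 and knockout-labelled replicates 2 and 3 at 17.4, 24.6 and 25.7. The second, with 18.7%, placed control replicates 1 to 3 at -27.3, -9.72 and -2.22 and knockout-labelled replicates 1 to 3 at 18.8, 12.5 and 7.97. For any 1 component chance gives groups that do not overlap in 10% of cases. Spearman correlations between libraries ran from 0.94 to 0.98. Within the set of control replicates 1 and 3 and knockout-labelled replicate 1 the G3bp1 difference, knockout-labelled minus control, was 0.06 log2 units, and within the other it was -0.18. Within both sets Gldc lay higher, by 0.84 and 1.21, and Dbp lower, by -1.58 and -1.68, in the knockout-labelled libraries. Both genes were named because their groups do not overlap. This order within the sets was therefore fixed beforehand and decides nothing about the sets.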

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

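The share of counts on transcript identifiers that matched no gene, which enter no comparison, was higher in each knockout-labelled library than in every control. It was 0.259%, 0.267% and 0.268% in knockout-labelled replicates 1 to 3 and 0.226%, 0.216% and 0.247% in control replicates 1 to 3. Chance gives groups that do not overlap, in either direction, in 10% of cases.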

How the results depend on the processing

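The alternatives without TMM, with protein-coding genes alone, with a term for the library division and with the length and GC trend removed were chosen after the data were seen. The counts of 0 genes higher and 0 lower held under 20 of 22 alternatives each. The minimum fold is counted among these 20 but could only return 0, since the main fit called 0 genes. DESeq2 called 7 higher and 5 lower; in simulated data it called 38 unchanged genes where edgeR called 17, and the cause of its calls was not tested. Leaving out 1 library gave 0 to 2 genes higher and 0 to 1 lower, the calls coming without knockout-labelled replicate 1. These were Mdh1, Saraf and Gm12918, outside the rule for named genes and chosen after their values were seen: Mdh1 measured 21.3 and 24.1 CPM in knockout-labelled replicates 2 and 3 and at most 0.44 in the other 4 libraries. Saraf measured 46.6 and 19.0 CPM in knockout-labelled replicates 2 and 3 and at most 0.17 in the other 4. In the reverse order, Gm12918 measured 0 CPM in knockout-labelled replicates 2 and 3 and 16.3 to 36.2 in the other 4. These are sums of estimated counts, and how reads were divided among near-identical copies was not tested. A sum near 0 therefore need not mean that the gene was silent. The smallest adjusted p over these settings ran from 0.00041 to 1.00. The G3bp1 difference ran from -0.38 to -0.08 with 1 library left out and turned to 0.0745 with library totals alone, which raised the median of all genes by 0.26; the adjusted p of G3bp1 ran from 0.31 to 1.00 over its 20 alternatives. The count of 10 lists became 0 with an estimated correlation, 0 with fry, 17 with library totals alone and 5 with the length and GC trend removed, and ran from 9 to 14 with 1 library left out. As mean log2 CPM differences, with 1 library left out, male-biased genes ran from -1.32 to 0.0847 (without control replicate 2), Kupffer cell and macrophage markers from -0.77 to 0.0687 (without control replicate 3) and interferon genes from 0.0272 to 0.63, the lowest, without knockout-labelled replicate 3, with the other direction in the test. The pericentral mean was 0.0542 with library totals alone, below that shift of 0.26, and the list was still called lower. Apart from the scaling and the library left out, the causes were not tested. The calls of ribosomal, respiratory chain and red blood cell genes held with each library left out, and those of the other 7 lists were lost without at least 1 library, controls and knockout-labelled alike. Whether replicate numbers pair the samples is not decided. Same-numbered libraries had correlations of deviations of 0.20, 0.27 and -0.14, and differently numbered ones of the 2 groups ran from -0.43 to 0.34. With the replicate block the counts were 0 genes higher, 0 lower and 10 lists, and G3bp1 was at -0.19. In that fit 719 genes had an unadjusted p under 0.05 by edgeR, in place of 568. The simulation changed 200 genes at this depth and number of libraries. In it edgeR called 10% of genes changed 1 log2 unit and 76% of those changed 2, so smaller differences would mostly be missed. These shares do not carry over to the data, since the adjustment is stricter where fewer genes are changed and 0 were called. Arntl, at a log2 difference of 2.36, did not pass over all genes by edgeR, so fitted differences above 2 can also fall below the threshold.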

Other observations

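All tests below were chosen after the result they bear on was seen, except the count of lists over other divisions of the libraries and removal of the length and GC trend from the clock index, which was chosen after the clock genes were seen but before its own result.

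Which transcripts of a gene carried the counts differed between sets of libraries that cross the groups: between control replicates 1 and 3 with knockout-labelled replicate 1 and the other 3 libraries, 67 transcripts had over 150 counts in each library of one set and under 8 in each of the other. The other 9 of the 10 divisions into sets of 3 gave at most 3 such transcripts, and bounds of 50 and 5 or of 500 and 10 gave 201 and 11 against at most 27 and 1. One transcript of Apoe, of 728 bases, had 5.13, 7.04 and 6.03 counts in the first set and 47470, 136966 and 125992 in the other, while the gene sum of Apoe stayed between 27826 and 42049 CPM. The gene sums of the 64 genes concerned had a median log2 range of 0.72 over the 6 libraries, under 1 for 49 of them, which is consistent with reads divided differently among transcripts of a gene for most of these genes, but not for Gm42742, whose sum was at most 0.053 CPM in the first set and at least 10.5 in the other, and Cyp2a5 and Per1 had ranges of 2.42 and 2.25. An exchange of knockout-labelled replicate 1 and control replicate 2 stays open, and no sample was regrouped: G3bp1 in control replicate 2, at 34.8 CPM, lies below the lowest of the first set at 40.5, as an exchange would need, but this is 1 gene whose order was seen first, and in the deposited TPM the sets overlap, with knockout-labelled replicate 3 at 4.67 and control replicate 1 at 4.32. Control replicate 2 itself was the lowest of the 6 libraries in TPM as well, at 3.50.

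The lower ribosomal and respiratory chain lists may follow transcript length. After removing each library's trend over length and GC content, fitted on genes outside both lists, 21.5% of the mean log2 difference of the ribosomal list and 22.1% of that of the respiratory chain list remained. The members have a median transcript length of 761 and 967 bases. The group label as the source is not decided, since 1 of the 3 knockout-labelled libraries lies within the controls for the ribosomal list. What gave the libraries their length trend, including whether genotype did, was not tested.

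Clock genes lay apart by limb on balance, the direction a shift of phase would give: of 6 genes of the BMAL1 limb 5 lay above 0, and of 13 genes driven through E-boxes and D-boxes 12 lay below 0, with 19 of the 21 list members assigned to limbs after their values were seen, so that no test of the pattern itself is given, and 3 of the 21 past the threshold adjusted over the list alone. The mean of the first minus that of the second was -1.78, 0.19 and -0.88 in control replicates 1 to 3 and 0.28, 1.09 and 1.09 in knockout-labelled replicates 1 to 3. Removing the length and GC trend left 101% of the difference of 1.64, which argues against that trend as the whole source. Within both sets of libraries described above the gap was at least 0.90, but this order follows from groups that do not overlap and decides nothing about the sets. Some signs also went with these sets, as in Ciart and Usp2, picked after their values were seen. Ciart measured 25.7, 3.18 and 26.9 CPM in control replicates 1 to 3. In knockout-labelled replicates 1 to 3 it measured 12.4, 1.86 and 1.80 CPM. Usp2 measured 43.7, 7.34 and 42.8 CPM in the controls and 24.8, 6.90 and 4.15 in the knockout-labelled libraries. Of the 21 list members, 4 lay higher and 2 lower without overlap between groups. How far the sets give the signs was not tested. A different time of day at collection may give the pattern by limb, as may the knockout. These 2 cannot be told apart because the labels give no time and the groups differ in genotype.

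With 10 divisions of the 6 libraries no share under 0.05 can be reached. The labelled division gave 0 genes, and the highest of the others gave 26, for the sets described above, with 2350 genes at an unadjusted p under 0.05, which points to a structure of the samples other than the labels. For gene lists the labelled division gave 10, the highest other gave 18, and all 10 gave at least 10, so calls by camera with the preset correlation were as frequent without regard to the labels.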
